A study of Homo sapiens with 5 samples.

How the data were processed

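Small RNA of isolated epithelial cells was, per the labels' protocols, size-selected, tailed, tagged, stained with Cy5 and hybridised by a service company to 1 array per group. The study's design text speaks of quadruple replicates, and the files show 4 spots per miRNA on each of 5 arrays; spots on 1 array are technical repeats and were never counted as samples. The deposited scanner files hold the mean intensity of each of 3968 spots, of which 3576 belong to 894 human miRNAs; this intensity is not background-subtracted, since 100 blank spots read 46.1 to 72.6 on average. The deposited series table holds 1 intensity per miRNA and array from the authors, from which background was removed and which was normalized between arrays by a method not given in the sources used here. Its column medians are 14 to 15, it is on a linear scale with no centring, and it correlated with the scanner signals with a Spearman rho of 0.987 to 0.997 across miRNAs.

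Scanner intensities were background-corrected with normexp (offset 50) on all spots of an array, taken to log2 and averaged over the 4 spots of each miRNA; control spots were then left out and the arrays were quantile-normalized. Quantile normalization gives the same set of levels to every array, so a difference is relative to the other miRNAs and a rank decides the level of the brightest ones. A miRNA counted as detected on an array where its mean spot intensity exceeded the mean plus 3 SD of the blank spots, a limit of 133 before culture, 124 and 100 on the control arrays and 84.7 and 66.0 on the Bt2cAMP arrays. Of the 894 miRNAs, 199 were detected on all 5 arrays and 573 on none, and 275 detected on at least 2 arrays were tested. The brightest miRNA spot read 38541.5, and the median SD over spots of detected miRNAs was 0.11 to 0.12 on the log2 scale. The number of arrays limits the precision.

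The 5 arrays were fitted with limma (lmFit, eBayes with an intensity trend) in an additive model of treatment and time, with a term of its own for the array before culture, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The moderated array SD was 0.19 (median, log2), with 21.6 prior degrees of freedom. P-values measure the spread between single arrays, which may be technical. Differences between single arrays carry a technical SE over spots and no p-value; counts of 2-fold differences require spots that do not overlap. A miRNA detected on 1 side only is given as at least N-fold, the brighter side against the detection limit of the dimmer array or the dimmer side's own signal, whichever is higher. For 23 lists of miRNAs the median difference was set against 10000 random lists of the same size, drawn from the 30 miRNAs nearest in level to each member. Random lists do not keep the likeness of related probes, so percentiles of families may be too extreme. From these lists miR-199b-3p and miR-923 have no probe under those names; mature miR-199b-3p has the sequence of miR-199a-3p, whose probe reads both, and miR-923 was not analysed here.

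The groups, tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took every miR-200 family member; the 10 highest and 10 lowest mean differences for Bt2cAMP and for culture, and 5 each way for time and for the change of the Bt2cAMP difference, among miRNAs detected on the arrays concerned and, for the first 3, with the same sign in both pairs; up to 5 each way detected on 1 side only; the 5 highest levels per array; up to 4 members per list; and every miRNA past the threshold where 20 or fewer passed. Some further list members are named because they passed the test, and were chosen after their values were seen.

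On data simulated for the Bt2cAMP effect from the levels and variances of the 275 tested miRNAs, with 60 changed in each of 20 runs, the fit recovered 44% of changes of 0.5, 96.5% of changes of 1 and 100% of changes of 2 on the log2 scale, and 3.02% of calls were false. Of 200 lists drawn at random, 6.5% lay outside the central 95 percent of their matched lists. These simulations take the model's own assumptions, among them that miRNAs vary independently.

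Alternatives were percentile (75th, over miRNAs detected on all arrays), cyclic loess and no normalization, no background correction, an offset of 16, the median of spots, other detection filters, the deposited table, other eBayes settings, and other terms and arrays in the fit. Added after seeing the data were blank-spot subtraction, scaling to spike-in spots, removal of a quadratic trend with GC content from each array, and a detection limit from 16 background spots. The spike scale was the mean over the probes PUC2PM-20B, a2-PUC2PM-20B and a3-PUC2PM-20B, with 16 spots each. Control probes did not all move alike. From control to Bt2cAMP at 48 h PUC2PM-20B went from 2618 to 1866, but Ctr09-3P from 12007.4 to 23027.5 and Ctr07-3P from 7548 to 11580. At 96 h each of these was lower with Bt2cAMP. Scales from other control probes were not run. GC content was taken from the sequences in the files. Genes that neighbour each other were found by matching names of mature miRNAs to gene symbols of the RefSeq table for assembly GRCh38.p14, where 252 of 275 tested miRNAs matched; neighbours lay within 10000 bases of each other. R 4.3.3 with limma 3.58.1 was used for analysis and Python 3.11.15 with matplotlib 3.10.9 for plots.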

Results

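MicroRNA levels were measured in epithelial cells isolated from human fetal lung explants, pieces of tissue kept alive in serum-free Waymouth's medium. The title of the study concerns the miR-200 family, small RNAs typical of epithelia, in the differentiation of type II cells, which make lung surfactant. Cells were taken before culture, after 48 h and 96 h of culture without addition (control), and after the same times with 1 mM dibutyryl cAMP (Bt2cAMP), a cell-permeable analogue of the second messenger cAMP. Each of the 5 groups was measured on 1 single-colour array with 4 spots for each of 894 human miRNAs. Detected miRNAs numbered 265 before culture, 229 and 262 on the control arrays at 48 h and 96 h, and 234 and 285 on the Bt2cAMP arrays at 48 h and 96 h. Summed miRNA intensity was 617865 before culture, 399324 and 443154 on the control arrays, and 199443 and 209154 on the Bt2cAMP arrays, so the treated arrays were the dimmest. Probes differ in affinity, so levels rank probe signals and not amounts. The highest normalized signals before culture belonged to miR-1246, miR-1974, miR-26a, miR-1826 and miR-1975, and miR-21 was among the 5 highest on the control arrays at 48 h and 96 h and on the Bt2cAMP array at 96 h. Several of these entries, such as miR-1974 and miR-1826, are listed here as fragments of other RNAs.

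The first comparison asked how the 5 members of the miR-200 family behaved with Bt2cAMP. Only miR-200c rose, by 1.04 on the log2 scale, or 2.05-fold (SE 0.17, adjusted p = 1.17e-04 by limma). It was 1.10 higher at 48 h (technical SE 0.10) and 0.98 higher at 96 h (technical SE 0.14), and its level was 10.52 before culture, 10.76 and 11.17 in control culture and 11.86 and 12.14 with Bt2cAMP. Its near neighbour in sequence, miR-200b, was 0.44 higher (SE 0.17) with an adjusted p of 0.0532 by limma, and passed when adjusted over the list alone, where 2 of the 5 members passed. Over all miRNAs it passed as higher in 7 alternatives, among them percentile scaling (0.73) and GC trend removal (0.75), and stood at -0.0324 with spike scaling and -0.68 without normalization. The other members did not pass, with differences of 0.09 for miR-200a, -0.03 for miR-141, which shares the locus of miR-200c, and -0.09 for miR-429; without normalization these 3 passed as lower (-1.15, -0.68 and -1.12). The family's median of 0.09 lay at percentile 47.4 of random lists matched on level, and was 0.28 with percentile scaling, 0.26 with a GC trend removed, -0.02 with loess, -0.24 with spike scaling and -0.68 without normalization. No member passed the test between before and after control culture or between 48 h and 96 h, over all miRNAs or adjusted over the list alone. Without normalization all but miR-200c passed as lower after control culture, from -0.74 for miR-141 to -1.28 for miR-429, and miR-200c passed as higher (0.96) when all 4 cultured arrays were set against the array before culture. From 48 h to 96 h the family's median difference was 0.34, at percentile 99.5 of matched lists. Several other lists also lay near an end for time, so this percentile does not set the family apart. Near the top were culture and injury (99.99), miR-29 (99.79), miR-23/24/27 (99.28) and other epithelial miRNAs (98.33). Near the bottom were let-7 and muscle (both 0.01) and miR-34 with miR-449 (0.25). Some lists lay between, such as the miR-30 family (35). The rise of miR-200c depended on scaling: it was 1.30 and 1.09 with percentile and loess scaling, 0.54 and short of the threshold with spike scaling, and turned to -0.12 without normalization. A fit without a term for time gave it an adjusted p of 0.0609 by limma.

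**Figure D1:**
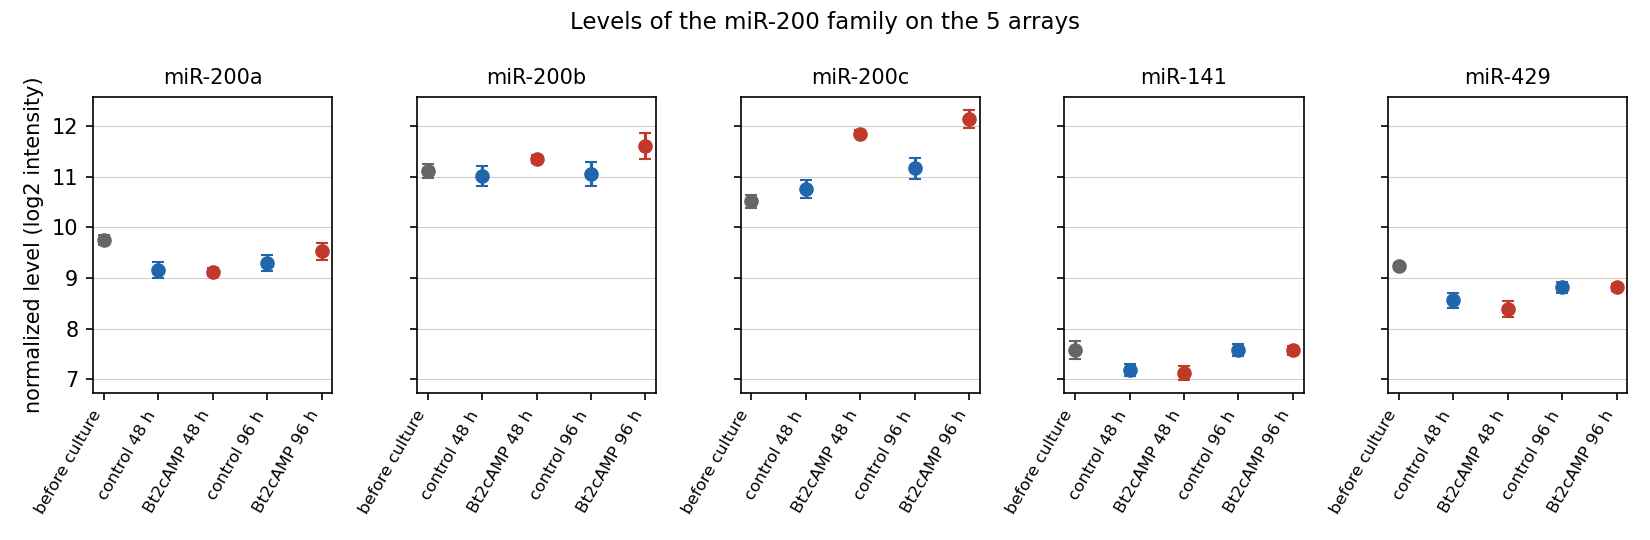
Normalized log2 levels of the 5 miR-200 family members on the 5 arrays (1 array per group). Points are means and bars are the SD of 4 spots on that array; grey is before culture, blue is control and red is Bt2cAMP. The level of miR-200c was 11.86 and 12.14 on the Bt2cAMP arrays against 10.76 and 11.17 on the control arrays, a difference that turned to -0.12 without normalization.

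With Bt2cAMP over both times, 89 of 275 tested miRNAs passed the limma threshold, 44 higher and 45 lower. The deepest falls were those of miR-451, a red blood cell miRNA, by 2.24 on the log2 scale or 4.72-fold (SE 0.20, adjusted p = 1.96e-08), and miR-1978, an entry for an RNA fragment, by 2.14 (SE 0.22, adjusted p = 2.15e-07). The mesenchymal miR-199a-3p fell by 1.65, or 3.13-fold (SE 0.17, adjusted p = 2.41e-07). Also lower were miR-374a (-1.37), miR-218 (-1.37), miR-1246 (-1.34), miR-146a (-1.32), miR-424 (-1.27), miR-10a (-1.12) and miR-494 (-1.11). Among the higher miRNAs, miR-575 led with 1.10 (2.14-fold, SE 0.21), followed by miR-320a with 1.06 and miR-200c. The close relatives miR-320c (0.96) and miR-320b (0.94) rose too, while miR-320d (0.30, adjusted p = 0.306 by limma) did not pass. Rises were also seen for miR-151-3p (0.94), miR-19b (0.92), miR-181a (0.83), miR-1974 (0.81) and miR-574-3p (0.79). Without normalization the 10 miRNAs named here as higher all stood below 0, from -0.0441 for miR-575 to -0.38 for miR-181a. Of the tested miRNAs 68 have another probe within 2 edits, among them miR-320a and miR-320b, miR-200b and miR-200c, and pairs in the miR-181, let-7, miR-29, miR-30 and miR-19 families, so counts of family members are counts of probes that are not independent. Of the calls, 15 fell at least 2-fold and 3 rose at least 2-fold, a balance that depends on scaling, as the counts at each time below show. Differences at 48 h and 96 h, which share no array, correlated across the 275 miRNAs with a Pearson r of 0.80 and a Spearman rho of 0.75, and 206 miRNAs had the same sign at both times; miRNAs are not independent replicates.

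**Figure D2:**
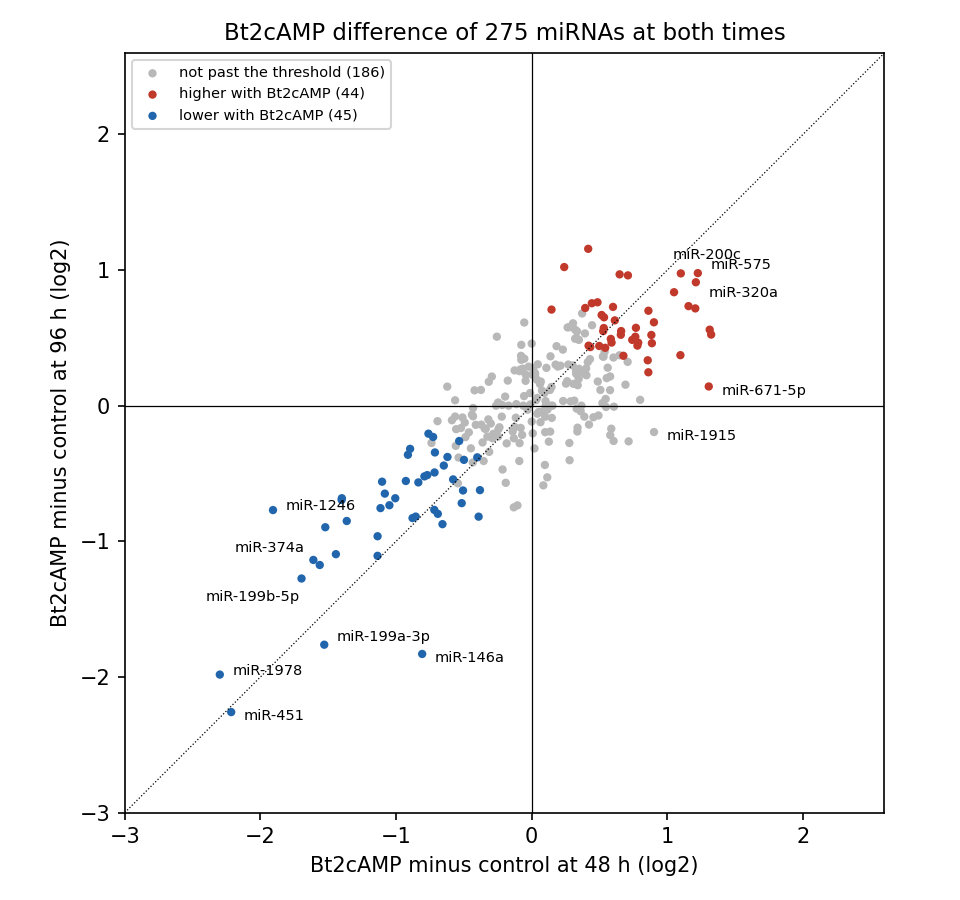
Bt2cAMP minus control at 48 h (horizontal axis, log2) and at 96 h (vertical axis, log2) for 275 tested miRNAs, 1 array per group. Red and blue points are the 44 higher and 45 lower miRNAs past the limma threshold, grey points the rest, and the dotted line marks equal differences; miR-451 and miR-1978 lie farthest to the lower left.

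The error of these tests is the time-by-treatment interaction plus array noise, with 1 residual degree of freedom before moderation across miRNAs, and nothing in the labels says how many donors or cultures stand behind an array. Without a term for time 5 miRNAs passed (miR-451, miR-1978, miR-199a-3p, miR-199b-5p and miR-374a, all lower), and the split of higher and lower calls was 132 and 30 with percentile scaling, 29 and 48 with loess, 0 and 9 with spike scaling and 1 and 234 without normalization, where the median difference of all tested miRNAs was 0.33, 0.03, -0.24 and -0.68 against 0.08 as reported.

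Grouped by lists, all 5 tested members of the miR-15 and miR-16 seed family, known for restraining cell growth, fell, with a median of -0.94 (percentile 0.11 of matched lists); examples are miR-424, miR-15b and miR-16 at -0.94. With Bt2cAMP, miR-15b and miR-199b-5p were below the detection limit at 48 h. In the mesenchymal list of miR-199 and miR-214, 3 of 4 members fell (median -1.13, percentile 0.03), miR-199a-3p, miR-199b-5p and miR-199a-5p by 0.77, while miR-214 stood at 0.13. Both endothelial miRNAs fell (percentile 0.55), miR-126 by 0.84 and miR-126*, which was below the detection limit on both Bt2cAMP arrays, at least 1.85-fold at 48 h and 1.71-fold at 96 h, and miR-451 was the only red blood cell member detected. Of the 5 tested muscle miRNAs miR-145 (-0.50) and miR-145* fell, the latter below the detection limit on both Bt2cAMP arrays, and miR-206 rose by 0.70 (list percentile 2.9). The imprinted 14q32 cluster, high in mesenchyme, had 1 fall (miR-494), 1 rise (miR-127-3p, 0.54) and 6 members that did not pass. In the miR-181 family 3 of 4 members rose (median 0.65, percentile 98.7): miR-181a, miR-181b at 0.67 and miR-181c at 0.62, a median that turned to -0.60 without normalization. Of the 9 let-7 members, which increase with differentiation, let-7b (0.67) and let-7c (0.53) rose; both were negative without normalization, and let-7c also with spike scaling, while 6 members rose (median 0.56) with a GC trend removed. For these lists the counts adjusted over the list alone were the same, except in the muscle list, where 3 members passed as lower.

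The miR-30 family had falls of miR-30c (-1.05) and miR-30b (-0.83) and a rise of miR-30d (0.59). The proliferation-linked miR-17~92 cluster and its paralogs had 3 rises (miR-19b, miR-93, miR-19a) and 3 falls (miR-363, miR-20a, miR-20b) among 12, with 3 and 4 adjusted over the list alone. In the family of miR-130 and miR-301 miR-130b rose by 0.66 and miR-301a, below the detection limit with Bt2cAMP at 48 h, fell. Single members passed in the miR-29 family (miR-29a, -0.61; 3 adjusted over the list alone), the family of miR-34 and miR-449 (miR-34a, lower and below the detection limit with Bt2cAMP at 48 h), the miR-23/24/27 group (miR-24, 0.60) and the miR-125, miR-99 and miR-100 group (miR-99a, -0.57; none adjusted over the list alone). Of miRNAs often induced in culture and injury, miR-146a, miR-146b-5p (-0.60) and miR-21 (-0.48) fell; with a GC trend removed only miR-146a passed, miR-146b-5p standing at -0.43 and miR-21 at -0.17. That removal also ended, among others, the calls of miR-29a (-0.43, adjusted p = 0.0536 by limma), miR-24 (0.48, adjusted p = 0.0568 by limma), miR-20a (-0.43), miR-127-3p (0.37), miR-1826 (-0.37), miR-301a (-0.25) and miR-1975 (0.23), whose differences shrank but kept their sign, and gained others, among them miR-182 (0.46), miR-205 (-0.45) and miR-99b (-0.55). As reported, neither the other epithelial miRNAs (miR-203, miR-205, miR-182, miR-375 and miR-31) nor the hypoxia miRNA miR-210 passed. No member of the miR-302 cluster, white blood cell or CREB-linked lists was detected on enough arrays to be tested. Among 11 tested entries for RNA fragments, a sign of RNA quality, miR-1974 and miR-1975 rose and miR-1978, miR-1246, miR-1977 and miR-1826 fell, with 2 and 5 adjusted over the list alone. Base composition went with direction: of 45 lower miRNAs 36 came from the 101 with the lowest GC content and 1 from the 86 with the highest, against 12 and 13 of the 44 higher ones.

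**Figure D3:**
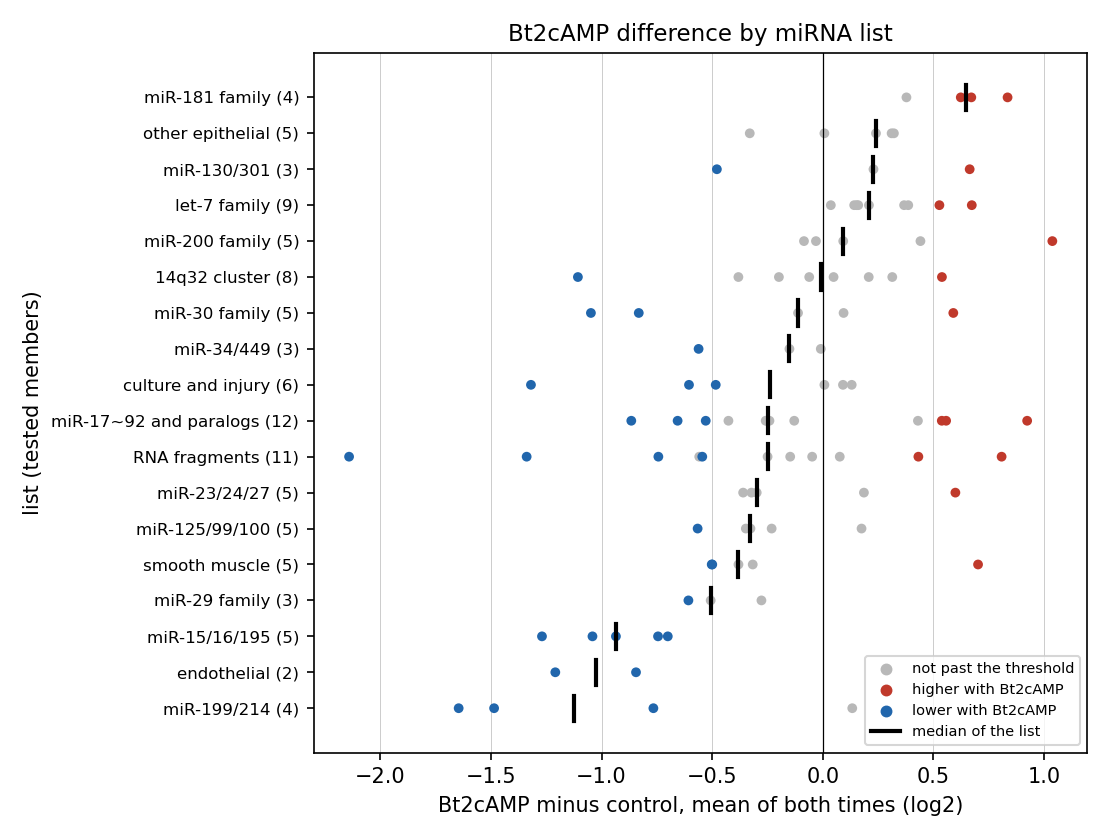
Bt2cAMP minus control as the mean of both times (horizontal axis, log2) for the tested members of each list with 2 or more such members. Each point is 1 miRNA, coloured by its side of the limma threshold, and black bars are list medians. The bars of miR-199 with miR-214 (-1.13), endothelial (-1.03) and miR-15 with miR-16 (-0.94) lie lowest. That of miR-181 (0.65) lies highest and turned to -0.60 without normalization. The endothelial bar includes miR-126*, below the detection limit on both Bt2cAMP arrays, and the miR-199 bar miR-199b-5p, below it at 48 h, so their exact positions are uncertain.

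Taken at each time alone, with 1 array per group and no test, more miRNAs stood at least 2-fold apart at 48 h, 10 higher and 19 lower with Bt2cAMP, than at 96 h, where 3 were higher and 9 lower. Without normalization the order turned, with 0 and 84 at 48 h and 0 and 104 at 96 h, and with percentile scaling more were higher than lower, 20 and 11 at 48 h and 8 and 5 at 96 h. The mesenchymal miR-199b-5p was detected in control culture but not with Bt2cAMP at 48 h, at least 3.18-fold lower, and miR-15b at least 2.45-fold lower. On the side of Bt2cAMP alone, miR-584 was at least 1.81-fold higher at 48 h and miR-122, a liver miRNA, at least 1.88-fold higher at 96 h. The Bt2cAMP difference changed by 2-fold or more between the times for 4 miRNAs. It weakened for miR-1246, from -1.91 to -0.77, and deepened for miR-146a, from -0.81 to -1.83. It shrank from 1.31 to 0.14 for miR-671-5p and went from 0.90 to -0.19 for miR-1915. These changes between times have no test, since 1 array per group leaves no error for them.

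Control culture was compared with cells before culture. The labels do not say whether these cells share a donor, so a difference of donor or array cannot be told apart from one of culture. Only 1 array was taken before culture, so the error of these tests comes from the cultured arrays alone. The largest rises were those of miR-21, a miRNA often induced by culture and injury, by 1.96 or 3.88-fold (SE 0.19, adjusted p = 2.13e-07 by limma), and miR-146a, induced in inflammation, by 1.76 or 3.39-fold (SE 0.28, adjusted p = 1.69e-04 by limma). Also higher were miR-29a, of a family with matrix gene targets, by 1.40, miR-762 (1.38), miR-146b-5p (1.21), miR-1279 (1.19), miR-1183 (1.09), miR-638 (1.04), miR-1972 (1.01) and miR-1978 (0.94). The largest fall was that of miR-617, by 2.57 or 5.95-fold (SE 0.28, adjusted p = 5.26e-07 by limma), ahead of miR-564 (-1.74), miR-601 (-1.60), miR-19a (-1.09), miR-449b (-1.02), miR-145 (-0.94), miR-575 (-0.91), miR-126 (-0.85), miR-140-3p (-0.82) and miR-1 (-0.77). In all, 37 miRNAs passed, 18 higher and 19 lower.

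By list, 3 of 6 culture and injury miRNAs rose (miR-21, miR-146a and miR-146b-5p), and the list's median of 0.86 lay above all matched lists. Of 5 muscle miRNAs, miR-145, miR-1, miR-143 (-0.65) and miR-145* (-0.57) fell, and the list's median of -0.65 lay below all matched lists. In the family of miR-34 and miR-449, linked to ciliated cells, miR-449b and miR-449a (-0.75) fell, and in the miR-29 family miR-29a and miR-29b rose, the latter detected on the control array at 96 h alone among these 3 arrays. The endothelial miR-126 fell while miR-126* stood at -0.22. None of the members of the miR-199, 14q32, let-7, miR-30, miR-15 or miR-181 lists passed. Adjusted over the list alone, the counts changed by 1 rise in the family of miR-34, 1 rise and 1 fall in let-7, 2 rises in the miR-23 group, 1 rise for miR-210, and 1 rise and 1 fall among the RNA fragments, where 2 rose and 2 fell over all miRNAs. The single array before culture is assumed to vary like the others, and the control arrays enter this comparison and that with Bt2cAMP with opposite signs, so chance alone sets the results of both against each other. Higher and lower calls numbered 34 and 23 with percentile scaling, 0 and 1 (miR-617) with spike scaling, and 12 and 163 without normalization, where the median difference was 0.05, -0.21 and -0.51.

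Between 48 h and 96 h of culture, over both treatments, 4 miRNAs passed. The matrix-linked miR-29a rose by 1.27 or 2.40-fold (SE 0.22, adjusted p = 0.00171 by limma), its relative miR-29b rose from below the detection limit on both arrays at 48 h to above it at 96 h, and the fragment entry miR-1246 rose by 1.07. The muscle miRNA miR-145 fell by 0.84 or 1.79-fold (SE 0.18, adjusted p = 0.00854 by limma). Adjusted over the list alone, all 3 members of the miR-29 family were higher. Other large differences did not pass, including those of miR-494 (0.65), miR-1279 (0.59), miR-146a (0.56), let-7e (-0.59), miR-214 (-0.59), miR-320d (-0.51) and let-7f (-0.50). The let-7 family had a median of -0.38 and the muscle list one of -0.44, both at percentile 0.01 of matched lists. Of each, 3 members were lower when adjusted over the list alone. The let-7 probes are close in sequence and miR-145 and miR-145* come from 1 hairpin, while random lists hold unrelated miRNAs, so these percentiles may be too extreme. The culture and injury list had a median of 0.39 (percentile 99.99) and 3 members higher when adjusted over the list alone, and the miR-199, 14q32 and red blood cell lists had 1 lower, 1 higher and 1 higher. At an unadjusted p under 0.05, 35 miRNAs passed, and 2 rises and no fall passed with loess scaling, 11 rises and no fall without normalization, and none with spike scaling, an offset of 16, the median of spots, no detection filter or no term for treatment.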

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

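The tests on cell shares were chosen after the result was seen, and those on GC content before. Opposite signs were looked for only in the miR-200 family and the miRNAs named for the change of the Bt2cAMP difference. Of these, 3 had Bt2cAMP differences of opposite sign at 48 h and 96 h, each by more than 2 technical SE. The change itself was not tested, and other miRNAs were not searched. The Bt2cAMP difference at 48 h and 96 h was -0.26 and 0.51 for miR-564, 0.90 and -0.19 for miR-1915, and 0.71 and -0.26 for miR-324-3p. Among control spots outside the comparisons, the 6 probes for 5S ribosomal RNA carried signal, and relative to the miRNAs their mean Bt2cAMP minus control differences were -1.11, 0.0229, 0.47, 0.62, 1.62 and 1.42 for hsa-5S-b1 to hsa-5S-b6. The last 2 probes read 34186 to 42777 and 50580 to 53236 on all arrays while the miRNAs dimmed, as a probe at its ceiling would. They levelled at different readings, and hsa-5S-b5 read 34186 in control and 42777 with Bt2cAMP at 96 h. A ceiling was not tested, so whether their 2 differences can be read as amounts is not known.

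Some mesenchymal and vascular miRNAs were lower with Bt2cAMP over both times: 3 of 3 tested endothelial and red blood cell members and 3 of 4 members of the list of miR-199 and miR-214 fell. A smaller share of mesenchymal cells would lower miRNAs made mainly by those cells. Of 17 tested members of the mesenchymal lists 6 fell, 9 did not pass and 2 rose, miR-206 and miR-127-3p. The rule of this test, set after the result was seen, counted any such rise against a smaller share. In 17 alternatives miR-206 kept its call in 13 and miR-127-3p in 8. Without normalization both turned to falls (-0.54 and -0.66), but the median of all tested miRNAs was lower still. That change of sign therefore says little about their rise relative to other miRNAs. With spike scaling miR-127-3p stood at -0.0393, and it missed the threshold with a GC trend removed. Members also spread: miR-214 stood 1.78 (SE 0.26) above miR-199a-3p, whose probe also reads miR-199b-3p from another locus. Neither the 2 rises nor this spread decides the question, because a smaller share lowers each miRNA only as far as its signal comes from those cells. A smaller share of mesenchymal cells thus stays open, as the whole cause or as a part. A GC trend common to all tested miRNAs does not account for the whole of the vascular and miR-199 falls. All 6 stayed past the threshold once it was removed. The median of the miR-199 and miR-214 list went from -1.13 to -1.11, the endothelial one from -1.03 to -0.87, and miR-451 from -2.24 to -1.92. These 6 were picked as falls on the same arrays, and a GC effect steeper than the common trend was not tested. A smaller share of endothelial and red blood cells cannot be told apart from regulation, because only 3 members were tested; the falls of miR-126 and miR-126* differed by 1.51 SE, but miR-126* was below the detection limit on both Bt2cAMP arrays, so that gap decides nothing. An effect of Bt2cAMP on these miRNAs in epithelial cells stays open and untested, as does a share of several cell types at once, since the cells were isolated from tissue and the purity is not given in the sources used here.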

How the results depend on the processing

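Blank-spot subtraction, spike scaling, GC trend removal and the limit from background spots were chosen after seeing the data. No paired analysis was possible because the labels carry no donor or culture numbers; arrays are matched by time alone, through the term for time. Each alternative changed 1 choice, except the deposited table, which replaces background correction, normalization and spot summary together. Of the single miRNAs and list medians, 1434 values stayed, 272 lost significance, 14 gained it, 41 without a test moved with the same sign and 43 changed sign. Of those 43, 29 were past a threshold before or after and the other 14 were all in the miR-200 family. A single miRNA that stayed kept its direction and side of the threshold. A list median has no test and stayed if it kept its sign and moved by less than the moderated array SD. Of the counts and family values, 172 stayed, 55 moved without a test, 14 shrank and 8 grew, and 5 family values among these changed sign. In every alternative in which they were tested miR-451, miR-1978, miR-199a-3p, miR-374a and miR-199b-5p stayed lower with Bt2cAMP and miR-617 lower after culture. For miR-200c with Bt2cAMP the adjusted p ranged from 1.82e-08 to 0.892 by limma. With 1 residual degree of freedom the moderation across miRNAs differs between alternatives, and the cause of each change below was not tested. Signal over background limits detection: 573 of 894 miRNAs passed the blank-spot limit on no array.

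Values below follow those reported, which were 89 calls for Bt2cAMP, 37 for culture and 4 for time. The 2-fold counts, higher and lower, were 10 and 19 for Bt2cAMP at 48 h, 3 and 9 at 96 h, 3 and 3 for culture at 48 h, and 14 and 8 at 96 h, with 4 changes of the Bt2cAMP difference. The miR-200 family medians were -0.04 and 0.23 for Bt2cAMP at 48 h and 96 h, and -0.39 and -0.07 for culture.

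With percentile scaling, calls were 162 for Bt2cAMP, 57 for culture and 8 for time; 2-fold counts were 20 and 11 for Bt2cAMP at 48 h, 8 and 5 at 96 h, and 5 higher for culture at 48 h; the family median was 0.30 for Bt2cAMP at 48 h. With cyclic loess, calls were 71 for culture and 2 for time, and 2-fold counts were 4 higher for Bt2cAMP at 48 h, 7 and 6 for culture at 48 h, 16 lower for culture at 96 h and 1 change of the Bt2cAMP difference. The family median for culture at 96 h was -0.28.

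Without normalization, calls were 235 for Bt2cAMP, 175 for culture and 11 for time. The 2-fold counts were 0 and 84 for Bt2cAMP at 48 h, 0 and 104 at 96 h, 0 and 57 for culture at 48 h, and 7 and 54 at 96 h. Family medians were -0.68 and -0.77 for Bt2cAMP at 48 h and 96 h, and -0.99 and -0.79 for culture. The Bt2cAMP median of the family was -0.68, and miR-200c stood at -0.38 for culture. Bt2cAMP differences that changed sign were those of miR-575 (-0.0441), miR-151-3p (-0.10), miR-200c (-0.12), miR-1974 (-0.17), miR-320a (-0.25), miR-320c (-0.26), miR-320b (-0.29), miR-574-3p (-0.35), miR-19b (-0.36), miR-181a (-0.38), miR-130b (-0.51), let-7b (-0.51), miR-181c (-0.52), miR-206 (-0.54), the miR-181 median (-0.60), miR-30d (-0.61), miR-127-3p (-0.66), miR-181b (-0.67), miR-200b (-0.68), miR-24 (-0.69), let-7c (-0.72), miR-93 (-0.78) and miR-200a (-1.15).

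With spike scaling, calls were 9 for Bt2cAMP, 1 for culture and 0 for time (1 at an unadjusted p under 0.05 by limma). The 2-fold counts were 0 and 70 for Bt2cAMP at 48 h, 1 and 15 at 96 h, 5 and 6 for culture at 48 h, and 8 and 38 at 96 h, with 30 changes of the Bt2cAMP difference. Family medians were -0.47 and -0.00712 for Bt2cAMP at 48 h and 96 h and -0.70 for culture at 96 h. Signs changed for miR-200a (-0.55), miR-200b (-0.0324), the family's Bt2cAMP median (-0.24) and miR-200c for culture (-0.0311), none past the threshold, and for miR-181b (-0.0340), miR-127-3p (-0.0393), miR-24 (-0.0417), let-7c (-0.0745) and miR-93 (-0.15).

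An offset of 16 gave 21 calls for culture and 0 for time (31 unadjusted), with 5 higher for Bt2cAMP at 96 h, 9 and 7 for culture at 48 h and 15 lower at 96 h. The median of spots gave 57, 10 and 0 calls for Bt2cAMP, culture and time (32 unadjusted for time), and no detection filter 45, 7 and 0 (71 unadjusted). Without a term for time 5 calls were left for Bt2cAMP, and without one for treatment 0 for time (2 unadjusted). All 4 cultured arrays against the array before culture gave 72 calls and turned miR-1978 to -0.13. The deposited table gave 7 higher for culture at 48 h and 13 lower at 96 h, and blank-spot subtraction 5 higher at 48 h. GC trend removal gave 8 higher for culture at 96 h, 2 changes of the Bt2cAMP difference and a family median of 0.18 for Bt2cAMP at 48 h. A 1.5-fold threshold gave 39 and 41 for Bt2cAMP at 48 h, 26 and 31 at 96 h, 22 and 19 for culture at 48 h, 31 and 32 at 96 h, and 19 changes of the Bt2cAMP difference.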

Other observations

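The tests of GC content and of genomic clusters were planned before their results were seen; that of pairs from 1 hairpin came after, as did the removal of such pairs from the cluster test and a fuller match of names to genes, made when a first run had shown no smaller gap. Members of 1 seed family, which share target motifs, went opposite ways with Bt2cAMP in 3 of 29 seed families with 2 or more tested members. In the family of miR-30, miR-30b and miR-30c fell while miR-30d rose; in that of miR-17, miR-20a and miR-20b fell while miR-93 rose; and in that of miR-130, miR-301a and miR-454 (-0.89) fell while miR-130b rose. Without normalization, where the median of all tested miRNAs was negative too, the rises of miR-30d, miR-93 and miR-130b turned to falls. That of miR-93 also did so with spike scaling.

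Opposite arms of 1 hairpin, chosen here after their values were seen, also parted: miR-424 fell by 1.27 while miR-424* rose by 0.63, and miR-195 fell by 0.74 while miR-195* rose by 0.59. The neighbours miR-200c and miR-141 differed by 1.07 in their Bt2cAMP difference.

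GC content may contribute to the parting of seed families: within families the difference rose by 0.45 per 10 percentage points of GC, with a two-sided permutation p of 2e-05 over 100000 shuffles within families. Whether GC content is the whole cause is not decided. After the GC trend was removed, 3 seed families still had members past the threshold both ways. Some of these calls were marginal, with an adjusted p of 0.0499 for miR-93 and 0.0430 for miR-30d by limma. Of the falls named above, those of miR-20a and miR-301a no longer passed. The GC trend was fitted over all tested miRNAs and not within families, so a steeper GC effect within families would remain. Regulation by genomic cluster stays open: over 112 pairs from neighbouring genes the mean gap was 0.52 against 0.57 when shuffled, a one-sided permutation p of 0.103, which misses the threshold. The bound set beforehand counted such a p against this explanation; that was dropped after the value was seen, because a missed threshold does not show that clusters have no part. Over 34 pairs matched by name to 1 hairpin the gap was 0.46 against 0.56, with a one-sided permutation p of 0.0371. The match also paired miR-181a-2* with miR-181a*, arms of different hairpins, and the value without that pair was not computed. GC content enters both the hybridisation of a probe and the sequence of a miRNA, and these arrays do not separate the effects.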
